A study of Danio rerio with 6 samples.

How the data were processed

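RNA was measured in 6 libraries of sorted zebrafish trunk cells in 3 groups of 2, slow muscle, untreated neural crest and cyclopamine-treated neural crest, and each library was assigned to its group from its label. The titles of both untreated neural crest libraries carry the word slow-twitch, while their tissue and source fields name neural crest, and they were taken as neural crest. The deposited log2 column of cyclopamine replicate 4 lacks the treatment in its header, while the labels and the count table give it; it was matched by sample number, and its values were recomputed from the counts of that library. Per the labels' protocols, embryos were reared at 28 °C, trunks were dissected by hand and dissociated with Accumax, polyA RNA was prepared with a stranded Illumina kit, and paired reads of 150 bp were sequenced on a NovaSeq instrument. The series' design text describes sorting both cell populations from the same doubly transgenic embryos. Slow muscle and untreated neural crest share the replicate numbers 1 and 2 in the labels, without a statement that a number marks the same embryos or day. The main test treats these libraries as unpaired.

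The deposited counts are whole numbers of reads per Ensembl gene, for 32520 genes of which 11265 were at 0 in all libraries. STAR, featureCounts, Subread and DESeq2 are named per the submitters' processing notes, without versions. The genome build, annotation release, strand setting and handling of multiply mapping reads are not given in the sources used here, so counts of near-identical genes and of overlapping or antisense genes are uncertain. The deposited log2 values equal log2 of the count divided by a DESeq2 size factor plus a pseudocount of 1, as checked by recomputing them from the counts, so they are no separate measurement. Gene symbols came with the count table, except for 80 genes without one.

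The main test was edgeR 4.0.16 (quasi-likelihood, default settings) on the counts in R 4.3.3, with TMM normalization and filterByExpr (minimum count 10, minimum total 15), which left 17701 genes. All 6 libraries entered a single fit with the 3 groups and no covariate, since 2 libraries per group leave little information on the spread, and the common dispersion was 1.132 with 2.94 prior degrees of freedom. Slow muscle and cyclopamine-treated neural crest were each compared with untreated neural crest. P values are two-sided and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. Levels are CPM, counts scaled to a common library size, over the TMM-normalised library size, as mean ± SD of 2 libraries, and log2 fold changes are edgeR's with the standard error derived from its test statistic. The untreated libraries serve both comparisons, and no overlap between the comparisons was computed.

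Before the data were examined, 40 gene lists were fixed, with 819 entries, of which 8 were matched through an older symbol and 17 were not matched. They cover Hedgehog targets and components, neural crest, pigment, sensory neuron and glial genes, migration and guidance, slow, fast and sarcomere muscle genes, muscle pioneers, myogenic factors, presomitic mesoderm, sclerotome, extracellular matrix, neural progenitors, ventral neural tube, neurons, notochord and floor plate, epidermis, erythroid, myeloid, endothelial and pronephric genes, cholesterol synthesis, p53, unfolded protein, immediate early, cell cycle, Wnt, Bmp, Fgf, Notch, retinoic acid and xenobiotic genes, 3 sets of Hox genes, and mitochondrially encoded and ribosomal protein genes. Each list was tested with camera (limma 3.58.1) on the edgeR object, with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 40 lists. camera compares a list with all other genes, and fry asks whether its genes move, on balance, one way. With an estimated correlation camera p rose even for lists whose estimate lay below 0.01. A call lost there is therefore not by itself evidence of correlated genes. Members were also adjusted over the list alone. The rule for named genes, fixed at the same time, took cdon, boc, prdm1a, sox10 and every tested Hedgehog gene, the 10 largest fitted changes per direction among called genes with at least 10 CPM in the higher group, no overlap between groups and a symbol that is not a clone name, and up to 4 members per list, namely the called ones with the largest changes or otherwise the most abundant. Genes outside the rule were chosen after their values were seen, among them sox6, lcp1, krt4 and cdh5 in slow muscle, her12 in the untreated libraries, col8a1a, ntd5, foxa2, noto and tbxtb in the closing section, and dusp4, spry4, fn1b, fstl1a, col4a1, pdgfra, ryr1b, cav3, en1b, cdh17, fgf8a and hoxd13a in the cyclopamine comparison. A single gene that the rule takes is not reported here.

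Alternatives fixed at the same time were no filter on low counts, a stricter filter (50 counts in 2 libraries), RLE and upper quartile scaling, DESeq2 1.42.0, a fit of the 4 libraries compared, robust estimation of the spread, limma on the deposited log2 values, a minimum log2 fold change of 1, the replicate number as a block, and each library left out in turn. Counts divided by the most common count of a library, and DESeq2 without each cyclopamine library, were added after seeing the data. With a library left out, the lone library of its group is assumed to vary like the others.

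Total counts were between 15355583 and 26441238 per library. Floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. The most common count was searched between 10 and 200 counts over running sums of 11 counts. Tested on simulated counts drawn from the means and library sizes of the real genes, with 40 genes changed per fold size, edgeR called 0% of genes changed 2-fold or 4-fold, 7.5% of those changed 8-fold, 30% of those changed 16-fold and 65% of those changed 64-fold in the slow muscle comparison, with 2 false calls, and 0%, 0%, 25%, 37.5% and 65% in the cyclopamine comparison, with 7 false calls. The simulated genes had the same dispersion in all groups, and the simulated libraries differed only in size. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Groups of 2 were too small for a test of single outlying libraries or for other splits of the samples. No library was left out of the main results.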

Results

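Bulk RNA sequencing was carried out on cells sorted from the dissected trunks of wild-type zebrafish embryos at 24 hours post fertilization. The embryos carried a pair of transgenes, sox10:mRFP, which marks neural crest cells, and prdm1a:eGFP, which marks slow-twitch muscle fibres and the muscle pioneers among them. The 6 libraries formed 3 groups of 2, namely slow muscle (replicates 1 and 2), untreated neural crest (replicates 1 and 2) and neural crest from embryos kept in 100 µM cyclopamine from 50% epiboly to 24 hours (replicates 3 and 4). Cyclopamine is a plant alkaloid that blocks Smoothened, the membrane protein through which Hedgehog signals enter the cell. No vehicle was stated for the untreated embryos.

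Total counts per library were 24358588 and 26441238 for slow muscle, 17504692 and 15355583 for untreated neural crest, and 20973884 and 18781774 for cyclopamine neural crest. Between 13249 and 17275 genes had at least 1 count, the fewest in cyclopamine replicate 4. Between 559 and 618 genes per library had 1 to 9 counts. Above 10 counts the number of genes per count first stayed low and then rose to a local peak, at 44 and 39 in slow muscle, 36 and 38 in untreated neural crest, 39 in cyclopamine replicate 3 and 102 in cyclopamine replicate 4. Between 122 and 1164 genes per library stood at 0 counts against at least 100 counts in the replicate, the most in cyclopamine replicate 4. A count of 0 allows up to 3 counts, or 0.127 to 0.177 CPM (counts scaled to a common library size), by counting error only. If the peak count stands for a single starting molecule, 3 molecules correspond to 4.42 to 16.3 CPM, so levels below that range are poorly determined and groups at 0 are given here as levels without a fold. Rank correlations across genes between replicates were 0.902 in slow muscle, 0.931 in untreated neural crest and 0.754 in cyclopamine neural crest. The first principal component (65.4% of the variance) separated the slow muscle libraries from the neural crest libraries. The next (20.1%) set cyclopamine replicate 4, at 122.3, apart from the other 5 libraries, which lay between -57.3 and 20.6. The labels do not say that the replicates came from separate pools of embryos, so p-values measure only the spread between these samples, which may be technical.

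**Figure D1:**
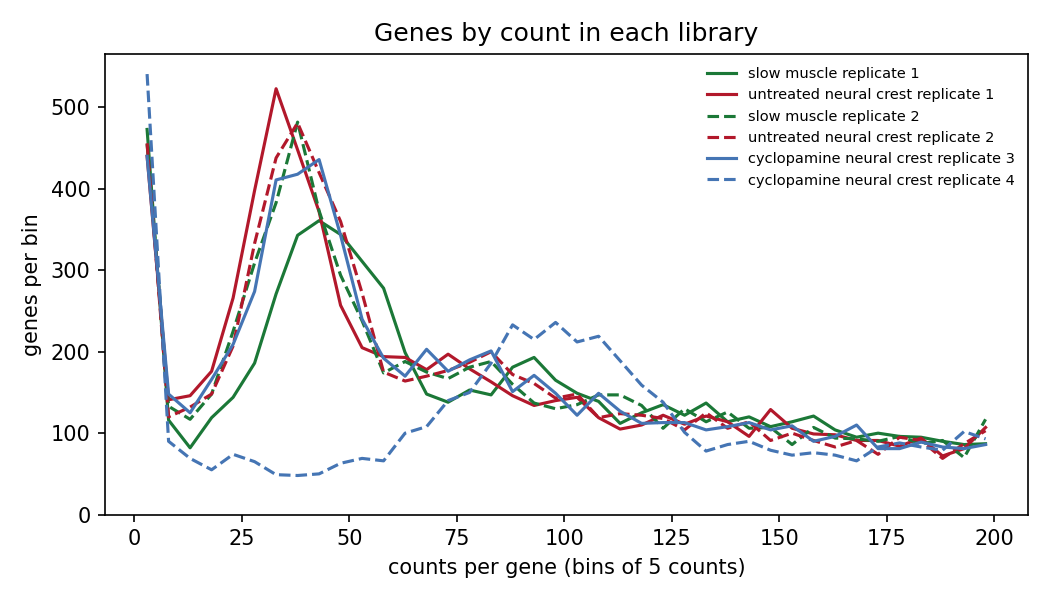
Number of genes (vertical axis, genes per bin of 5 counts) against their count (horizontal axis, counts per gene from 1 to 200) in each of the 6 libraries, 1 line per library. The lines start high at 1 to 5 counts, drop, and above 10 counts have a local peak near 36 to 44 counts in 5 libraries and near 102 counts in cyclopamine replicate 4.

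Slow muscle was compared with untreated neural crest to describe what each sorted population expresses, including the Hedgehog co-receptor genes cdon and boc named in the study's title. In edgeR's quasi-likelihood test 296 genes were higher and 155 lower in slow muscle, out of 17701 tested (n = 2 libraries per group). The reporter genes followed the sort. The neural crest regulator sox10 (ENSDARG00000077467) stood at 3.06 ± 1.65 CPM (mean ± SD) in slow muscle against 3231 ± 87.3 CPM in neural crest, a log2 fold change of -10.04 ± 0.71 (SE; edgeR adjusted p = 0.0119). prdm1a (ENSDARG00000002445), which encodes the transcription factor that directs slow fibre fate, stood at 1058 ± 5.2 CPM against 139 ± 9.2 CPM, a log2 fold change of 2.93 ± 0.42 (edgeR adjusted p = 0.0325). The slow myosin heavy chain gene smyhc1 was the most abundant gene in slow muscle, at 33510 ± 16770 CPM against 53.05 ± 8.38 CPM (log2 fold change 9.30 ± 1.54, edgeR adjusted p = 0.0432).

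Muscle genes were higher in the slow muscle sort. Of 8 tested slow muscle genes 4 were called higher, and all 8 were when p was adjusted over the list alone. The camera test of the list against all other genes gave an adjusted p of 1.99e-07, and adjusted p = 0.301 with an estimated correlation. smyhc3, another slow myosin heavy chain gene, had 0 counts in both neural crest libraries against 332 ± 158 CPM in slow muscle. Of 48 sarcomere and muscle function genes 18 were called higher, and 43 adjusted over the list alone (camera adjusted p = 2.09e-21, and adjusted p = 0.336 with an estimated correlation). Among them cav3, which encodes the muscle caveolin (219.6 ± 104 CPM), and the nebulin-related gene nrap (177 ± 129 CPM) had 0 counts in neural crest. Of 18 fast muscle genes 2 were called higher, ryr1b (345 ± 136 against 6.49 ± 1.95 CPM), which encodes a calcium release channel, and the fast troponin T gene tnnt3a (144 ± 92.8 against 3.64 ± 2.46 CPM). Adjusted over the list alone, 6 fast muscle genes were higher and 1 lower (camera adjusted p = 0.00128, and adjusted p = 0.434 with an estimated correlation). The lower one was sox6, a transcription factor of fast fibres. Reads of the near-identical smyhc genes and of the actin genes may be split between copies, since the handling of multiply mapping reads is not given in the sources used here.

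Engrailed genes mark the muscle pioneers, and 1 of 3 tested was called higher, 2 adjusted over the list alone (camera adjusted p = 0.0143, and adjusted p = 0.386 with an estimated correlation). en1a stood at 40.9 ± 16.4 CPM against 0 counts in neural crest. Of 18 myogenic factors 3 were called higher and 2 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0241, and adjusted p = 0.454 with an estimated correlation). The myocyte enhancer factor genes mef2d (1172 ± 77.6 against 44.8 ± 2.11 CPM) and mef2cb (334 ± 42 against 36.2 ± 7.1 CPM) were higher. pax7a and pax7b, listed here for muscle progenitors and also expressed in crest-derived yellow pigment cells, were lower. pax7b stood at 3.93 ± 1.61 against 628 ± 85 CPM (edgeR adjusted p = 0.0119) and pax7a at a single count in slow muscle against 351 ± 20.3 CPM (edgeR adjusted p = 0.0119). The myogenic list was not called without slow muscle replicate 1 (camera adjusted p = 0.118), untreated replicate 1 (0.0794) or untreated replicate 2 (0.0619).

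Neural crest and pigment genes were lower in slow muscle. Of 17 neural crest genes 8 were called lower, and 10 adjusted over the list alone (camera adjusted p = 2.06e-09, and adjusted p = 0.301 with an estimated correlation). The crest transcription factor gene tfap2e stood at 0.296 ± 0.418 against 199.6 ± 0.571 CPM. Of 20 pigment lineage genes 9 were called lower, and 19 adjusted over the list alone (camera adjusted p = 1.29e-20, and adjusted p = 0.301 with an estimated correlation). The melanin synthesis gene tyr (547 ± 75.4 CPM in neural crest), the melanosome gene pmela (390.2 ± 61.6 CPM), the melanocyte regulator mitfa (276 ± 10.2 CPM), the melanosomal transporter gene slc45a2 (254 ± 23.1 CPM) and ltk (77.3 ± 8.42 CPM), a receptor needed for iridescent pigment cells, had 0 counts in both slow muscle libraries. The same held for cax1, trpm1b, mocos, pcdh9 and rab27b, which stood between 77.2 and 419 CPM in neural crest. With those 5 they had the largest fitted falls among the called genes that met the rule for named genes. The largest fitted rises under the same rule, besides smyhc3, cav3 and nrap, belonged to tnni1c, klhl41a, alpk3b, foxi3a, smpx, myoz2b and pfkpa. These genes had 0 counts in untreated neural crest and stood between 149 and 518 CPM in slow muscle. tnni1c encodes a troponin I and foxi3a a transcription factor of ionocyte precursors of the skin. Of the 451 called genes, 52 had 0 counts in both neural crest libraries and 33 had 0 counts in both slow muscle libraries. Of 8 glial genes 2 were called lower, foxd3 (6.1 ± 0.92 against 195 ± 35 CPM) and the neuregulin receptor gene erbb3b (6.61 ± 6.07 against 643 ± 29.1 CPM), both also on the neural crest list. Over the list alone 3 glial genes were lower and 1 higher (camera adjusted p = 0.0241, and adjusted p = 0.364 with an estimated correlation). The glial list was not called without slow muscle replicate 2 (camera adjusted p = 0.0689), cyclopamine replicate 3 (0.0757) or cyclopamine replicate 4 (0.101). Of 20 neuronal genes 1 was called lower, the axonal contactin gene cntn2 (5.37 ± 3.23 against 81.3 ± 3.98 CPM), and 2 adjusted over the list alone (camera adjusted p = 0.00355, and adjusted p = 0.454 with an estimated correlation).

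**Figure D2:**
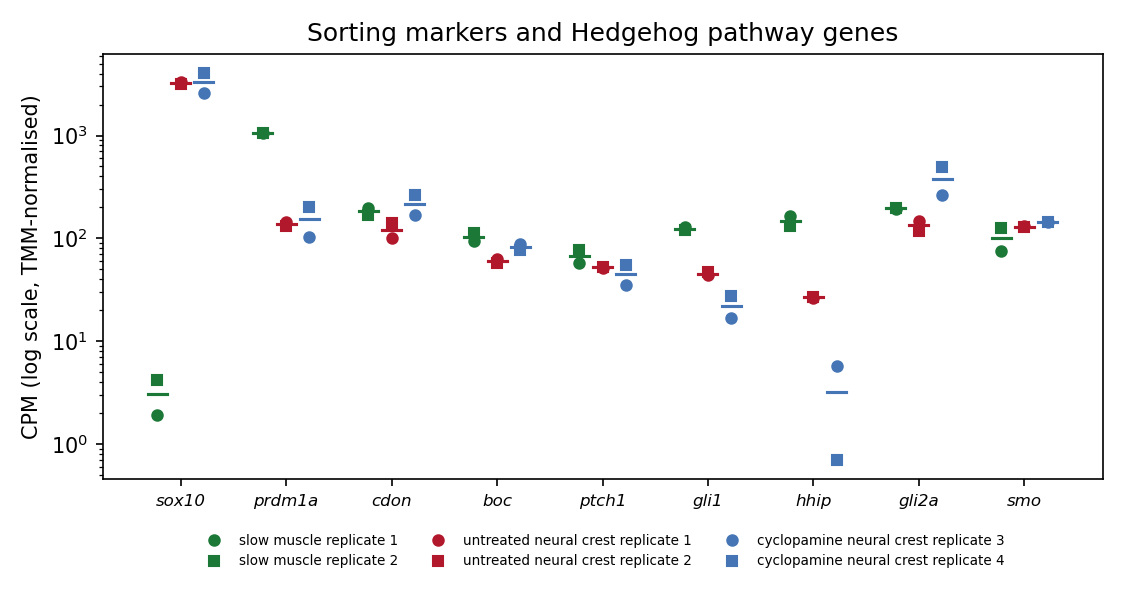
Level (vertical axis, CPM on a log scale, TMM-normalised) of the sorting markers sox10 and prdm1a and of 7 Hedgehog pathway genes in the 6 libraries. Points are libraries and bars are means of 2; gli1 and hhip lie higher in both slow muscle libraries and lower in both cyclopamine libraries than in the untreated neural crest libraries.

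Hedgehog target genes lay higher in slow muscle, where both libraries exceeded both neural crest libraries for gli1, hhip and ptch1. The transcription factor gene gli1 stood at 124 ± 5.31 against 45.2 ± 2.27 CPM (edgeR adjusted p = 0.113) and hhip, which encodes a ligand-binding antagonist of the pathway, at 147 ± 23.3 against 26.7 ± 0.675 CPM (edgeR adjusted p = 0.214). The receptor gene ptch1 stood at 67.3 ± 14.1 against 52.2 ± 1.22 CPM (edgeR adjusted p = 0.687). These genes did not pass over all genes in edgeR, while gli1 and hhip were higher adjusted over the list alone, and DESeq2 called gli1 (adjusted p = 0.0112) and hhip (0.0291). By fry the target list was called higher (adjusted p = 0.0277). The list as a set had a camera adjusted p of 0.0454, and adjusted p = 0.336 with an estimated correlation and 0.0766 with the replicate number as a block. It was not called without slow muscle replicate 1 (0.0831), slow muscle replicate 2 (0.117), untreated replicate 1 (0.11) or untreated replicate 2 (0.0947). Transcripts of the co-receptor genes were found in both sorted populations. The slow muscle libraries also held epidermal and endothelial transcripts, so these levels do not show which cells expressed them. cdon (ENSDARG00000061328) stood at 184 ± 19.8 CPM in slow muscle and 120.5 ± 27.7 CPM in neural crest (log2 fold change 0.61 ± 0.35, edgeR adjusted p = 0.396), and boc (ENSDARG00000074335) at 103 ± 12.9 and 60.0 ± 4.06 CPM (log2 fold change 0.79 ± 0.31, edgeR adjusted p = 0.243). DESeq2 gave adjusted p values of 0.323 for cdon and 0.0534 for boc, so neither difference passed with either tool. Of the 19 tested pathway components, 14 had a positive and 5 a negative fitted change, and none was called. fry called them higher as a set (adjusted p = 0.0277), while camera with an estimated correlation did not (adjusted p = 0.336). Over the list alone 1 (gli2b, 60.8 ± 1.22 against 9.85 ± 3.72 CPM) was higher (camera adjusted p = 0.0557, and between 0.0449 and 0.0464 without untreated replicate 1, cyclopamine replicate 3 or cyclopamine replicate 4). Among the other co-receptor and ligand release genes gas1a stood at 66.0 ± 17.9 against 14.5 ± 4.38 CPM, gas1b at 40.3 ± 9.62 against 10.7 ± 5.55 CPM. disp1 stood at 62.4 ± 7.86 against 26.1 ± 6.03 CPM, scube1 at 20.4 ± 1.49 against 2.41 ± 1.02 CPM and scube2 at 51.9 ± 19.1 against 21.5 ± 9.64 CPM (edgeR adjusted p between 0.112 and 0.593 for all 5). DESeq2 called gli2b (adjusted p = 3.82e-05), scube1 (0.00165), gas1a (0.031) and gas1b (0.0381) higher. The transducer genes smo (101 ± 36.6 against 129.6 ± 1.43 CPM), sufu (37.1 ± 4.27 against 45.3 ± 9.17 CPM), kif7 (41.1 ± 7.38 against 56.0 ± 1.05 CPM), gli2a (196 ± 4.55 against 133 ± 22.2 CPM) and gli3 (12.5 ± 7.03 against 18.9 ± 4.26 CPM) were not called (edgeR adjusted p between 0.461 and 0.748). stk36, lrp2a, scube3, shha, hhat and ihhb stayed below 10 CPM on average in both groups.

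Genes of extracellular matrix and cell guidance were also higher in the slow muscle libraries. Those libraries held epidermal and endothelial transcripts too, and which cells expressed the matrix and guidance genes was not resolved. Of 47 matrix and receptor genes 11 were called higher, and 23 were higher and 3 lower adjusted over the list alone (camera adjusted p = 2.37e-08, and adjusted p = 0.301 with an estimated correlation). The basement membrane genes col4a1 (308 ± 9.39 against 4.57 ± 1.32 CPM) and lama5 (1752 ± 576 against 30.9 ± 10.5 CPM) were among them. Of 51 migration and guidance genes 4 were called higher, and 14 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.301 with an estimated correlation). They included the semaphorin gene sema3e (34.8 ± 2.81 against 0.964 ± 0.276 CPM) and the ephrin gene efnb1 (74.1 ± 13 against 6.29 ± 3.79 CPM).

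The slow muscle libraries also held transcripts of other trunk tissues. Of 16 epidermal genes 1 was called higher, the keratin gene krt97 (1305 ± 449 against 12.9 ± 1.43 CPM). Over the list alone 11 were higher (camera adjusted p = 1.39e-06, and adjusted p = 0.427 with an estimated correlation). Of 14 endothelial genes 3 were called higher, among them the vascular transcription factor genes etv2 (206 ± 43.8 against 12.9 ± 0.103 CPM) and lmo2 (148 ± 5.42 against 5.82 ± 4.97 CPM). Over the list alone 13 were higher (camera adjusted p = 1.99e-08, and adjusted p = 0.336 with an estimated correlation). Of 9 pronephric genes 2 were called higher, cdh17 (94.4 ± 48.7 CPM against 0 counts) and atp1a1a.4 (113 ± 25.4 against 5.71 ± 0.0472 CPM), and 3 were over the list alone (camera adjusted p = 0.0036, and adjusted p = 0.334 with an estimated correlation). Of 15 presomitic mesoderm and somite genes 1 was called higher, also 1 over the list alone, the growth factor gene fgf8a (28.8 ± 0.384 CPM against 0 counts; camera adjusted p = 0.00946, and adjusted p = 0.386 with an estimated correlation). Of 7 sclerotome genes 1 was called higher, the matrilin gene matn4 (160 ± 57.8 against 20.1 ± 4.63 CPM), and 2 over the list alone (camera adjusted p = 0.0427, and adjusted p = 0.336 with an estimated correlation). The presomitic list was not called without slow muscle replicate 2 (0.0638), and the sclerotome list not without slow muscle replicate 1 (0.157) or untreated replicate 2 (0.106).

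In the other direction, the 9 myeloid genes were lower as a set although none was called lower (camera adjusted p = 0.0324, and adjusted p = 0.454 with an estimated correlation). The sole member past adjustment over the list alone was higher, cebpb at 293 ± 121 against 53.8 ± 0.758 CPM. The leukocyte actin-bundling gene lcp1 differed between the untreated libraries, at 13.9 and 102 CPM, and the list was not called without untreated replicate 2 (0.0566), slow muscle replicate 1 (0.0665) or slow muscle replicate 2 (0.109). The 14 erythroid genes were lower as a set with none called, 0 over the list alone too (camera adjusted p = 0.0465, and adjusted p = 0.622 with an estimated correlation). They were not called without slow muscle replicate 1 (0.051), slow muscle replicate 2 (0.25) or untreated replicate 2 (0.261). The globin gene hbae3 stood at 38.9 ± 25.6 against 48.2 ± 0.535 CPM. Of 27 cell cycle genes none was called, 0 over the list alone, and the set was lower in slow muscle (camera adjusted p = 0.001, and adjusted p = 0.37 with an estimated correlation). The proliferation marker gene mki67 stood at 215 ± 39 against 383 ± 29 CPM.

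Among stress and quality lists, 1 of 22 immediate early and heat shock genes was called higher, ier2b (318 ± 24.1 against 36.7 ± 6.67 CPM), and 4 over the list alone (camera adjusted p = 0.0241, and adjusted p = 0.334 with an estimated correlation). All 13 mitochondrially encoded genes had a positive fitted change with none called, 0 over the list alone (camera adjusted p = 0.0141, and adjusted p = 0.588 with an estimated correlation). They took 4.43% and 3.64% of counts in slow muscle against 2.52% and 2.80% in untreated neural crest. Both of these sets missed the threshold without slow muscle replicate 1 (0.0665 and 0.0831) or untreated replicate 1 (0.0699 and 0.0813). Of 8 xenobiotic response genes 1 was called higher, the quinone reductase gene nqo1 (147 ± 42.8 against 5.92 ± 1.51 CPM). Over the list alone 3 were higher and 1 lower (camera adjusted p = 0.0241, and adjusted p = 0.434 with an estimated correlation). That list was not called without slow muscle replicate 2 (0.0943) or untreated replicate 2 (0.0566). The 23 posterior Hox genes were higher as a set with none called, 0 over the list alone (camera adjusted p = 0.0204, and adjusted p = 0.334 with an estimated correlation; 0.0542 without slow muscle replicate 1 in the preset test). hoxb9a, the most abundant, nevertheless stood at 85.8 ± 17.6 against 189 ± 10.2 CPM.

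Besides lists described above, fry called ventral neural tube genes higher (adjusted p = 0.0164). By camera this list and the other remaining lists were not called as sets. Their camera adjusted p values were 0.0549 for unfolded protein and amino acid stress, 0.0827 for notochord and floor plate, 0.178 for cholesterol synthesis and uptake, 0.226 for retinoic acid targets and 0.298 for trunk Hox genes. They were 0.344 for ventral neural tube and motor neurons, 0.461 for cytosolic ribosomal proteins, 0.493 for the p53 response, 0.504 for anterior Hox genes and 0.636 for Bmp targets. The largest were 0.657 for neural progenitors and for sensory neurons, 0.669 for Fgf targets and for Notch targets, and 0.68 for Wnt targets. Some were called higher with a library left out, namely the unfolded protein list without slow muscle replicate 2 (0.0294), cyclopamine replicate 3 (0.0201) or cyclopamine replicate 4 (0.0215), the notochord list without untreated replicate 2 (0.0491), cyclopamine replicate 3 (0.0341) or cyclopamine replicate 4 (0.0441), and Notch targets without untreated replicate 1 (0.00866). Within them edgeR called the receptor gene notch3 higher (396 ± 28.7 against 115 ± 0.977 CPM; 1 neural progenitor over the list alone). It called the Wnt pathway transcription factor gene lef1 lower (31.3 ± 11.4 against 199 ± 21.6 CPM; 1 higher and 1 lower over the list alone). Adjusted over the list alone, 2 genes were higher on the unfolded protein list, 2 on the ventral neural tube list and 1 on the notochord list, 2 were higher and 2 lower on the Fgf list, and 0 passed on the others. Median, mean and test differed in sign for Wnt, Notch, Bmp and Fgf targets, neural progenitors, anterior Hox genes and ribosomal proteins.

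The number of called genes depended on the libraries in the fit. With only the 4 libraries compared edgeR called 2483 genes. That fit leaves out the cyclopamine libraries, whose difference from each other enters the spread shared by the 3 groups in the main fit. edgeR called 0 genes without slow muscle replicate 1 (1947 at an unadjusted p below 0.05), untreated replicate 1 (2060) or untreated replicate 2 (1997). It called 39 without slow muscle replicate 2, 2285 without cyclopamine replicate 3 and 2353 without cyclopamine replicate 4, while DESeq2 on all 6 libraries called 2756. With upper quartile scaling 52.4% of calls were higher in slow muscle against 65.6% with TMM, and the median log2 fold change over all genes moved from 0.08 to -0.16, so small differences are relative to that shift.

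Neural crest from cyclopamine-treated embryos was compared with untreated neural crest to look for a response to Hedgehog pathway blockade. The treated libraries are numbered 3 and 4 and the untreated ones 1 and 2. A response to the treatment therefore cannot be told apart from any difference in sort or day between these libraries. sox10 was expressed at 3322 ± 999 CPM with cyclopamine and 3231 ± 87.3 CPM without it (n = 2 libraries per group). Hedgehog targets lay lower with cyclopamine. hhip (ENSDARG00000060397) stood at 3.21 ± 3.54 against 26.7 ± 0.675 CPM, a log2 fold change of -3.05 ± 0.91 in edgeR (adjusted p = 0.835) and -3.08 in DESeq2 (adjusted p = 0.037). The level of hhip was 5.71 CPM in cyclopamine replicate 3 and 0.705 CPM in replicate 4. These levels lay near or below the 5.58 and 16.3 CPM estimated for 3 molecules in those libraries, so the size of the fall is poorly determined. The log2 fold change of hhip ranged from -5.23 to -2.22 over the settings run. The Fgf feedback gene dusp6, which encodes a phosphatase of ERK kinases, stood at 164 ± 8.73 against 563 ± 22.1 CPM, a log2 fold change of -1.78 ± 0.28 in edgeR (adjusted p = 0.584) and -1.76 in DESeq2 (adjusted p = 4.89e-10).

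edgeR called 0 of 17701 genes, with a smallest adjusted p of 0.45. An unadjusted p below 0.05 was reached by 767 genes, against 885 by chance if every gene could reach it. DESeq2 called 153 genes higher and 152 lower. The cyclopamine libraries differed strongly from each other, and single libraries moved these counts. Without replicate 3 edgeR called 145 genes higher and 450 lower and DESeq2 1761 and 3288. Without replicate 4 edgeR called 0 (1368 at an unadjusted p below 0.05) and DESeq2 647 and 734. 31.2% of genes had both cyclopamine libraries above or below both untreated ones, against 33.3% by chance if no libraries tie. Some tested genes, such as tnni1c and smyhc3, had 0 counts in all 4 neural crest libraries and could neither separate nor reach a small p. The chance figures of 885 and 33.3% are therefore too high here, and the comparison is not shown to fall below chance. In simulated counts for this comparison edgeR called 0% of genes changed 2-fold or 4-fold, 25% of those changed 8-fold and 65% of those changed 64-fold. Those counts had the same dispersion per gene in all groups and no library that stands apart, so the percentages are only a rough guide to the real data.

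Among the Hedgehog targets gli1 stood at 22.2 ± 7.61 against 45.2 ± 2.27 CPM (DESeq2 adjusted p = 0.513) and ptch1 at 45.2 ± 14.5 against 52.2 ± 1.22 CPM. As a set the targets were lower (camera adjusted p = 0.00216, and adjusted p = 0.416 with an estimated correlation), although hhip, gli1 and ptch1 did not pass over all genes or over the list alone. They were the sole list called by fry (adjusted p = 0.0471). The pathway components lay higher, 18 of 19 with a positive fitted change and 0 called, over the list alone too (camera adjusted p = 6.31e-06, and adjusted p = 0.247 with an estimated correlation). cdon stood at 214 ± 66.2 against 120.5 ± 27.7 CPM (log2 fold change 0.83 ± 0.36, edgeR adjusted p = 0.835). boc stood at 82.8 ± 8.85 against 60.0 ± 4.06 CPM (log2 fold change 0.46 ± 0.30, edgeR adjusted p = 0.835). DESeq2 called the activator gene gli2a (379 ± 161 against 133 ± 22.2 CPM, adjusted p = 0.0389) and scube1 (19.4 ± 8.65 against 2.41 ± 1.02 CPM, adjusted p = 0.016) higher. gli2b stood at 25.1 ± 6.07 against 9.85 ± 3.72 CPM, gli3 at 37.2 ± 16.2 against 18.9 ± 4.26 CPM. disp1 stood at 50.5 ± 27.4 against 26.1 ± 6.03 CPM, gas1a at 40.2 ± 34.6 against 14.5 ± 4.38 CPM and gas1b at 31.2 ± 12 against 10.7 ± 5.55 CPM. smo (145 ± 0.206 against 129.6 ± 1.43 CPM), sufu (58.4 ± 2.88 against 45.3 ± 9.17 CPM), kif7 (61.5 ± 14.1 against 56.0 ± 1.05 CPM) and scube2 (25.7 ± 31.2 against 21.5 ± 9.64 CPM) had edgeR adjusted p values between 0.968 and 1. The ligand gene shha was at 6.38 and 79 CPM in cyclopamine replicates 3 and 4 and at 3.16 and 0.177 CPM in the untreated libraries. lrp2a was at 37.4 ± 25.1 against 5.19 ± 7.34 CPM, and stk36, scube3, hhat and ihhb stayed below 10 CPM on average in both groups.

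**Figure D3:**
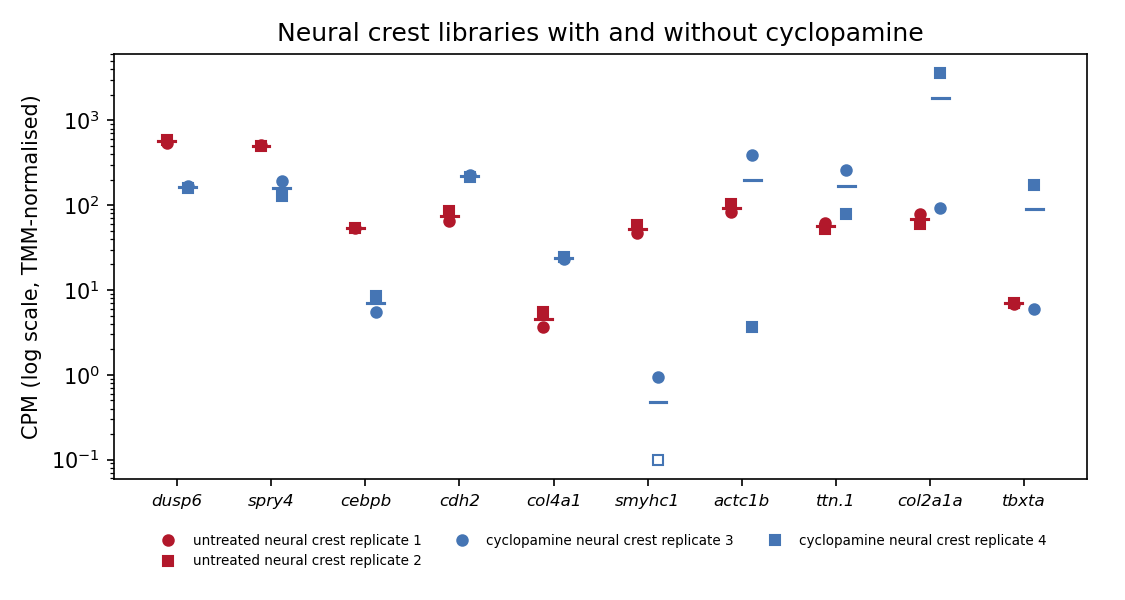
Level (vertical axis, CPM on a log scale, TMM-normalised) of 10 genes in the untreated and cyclopamine neural crest libraries. Points are libraries and bars are means of 2, and an open symbol marks a library at 0 counts. dusp6, spry4 and cebpb lie lower and cdh2 and col4a1 higher in both cyclopamine libraries, while actc1b, col2a1a and tbxta differ between the cyclopamine libraries.

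DESeq2 called 273 genes in the same direction with all 6 libraries and without either cyclopamine library, 126 higher and 147 lower, and 167 of them had 0 counts in both libraries of one group. The genes of this paragraph other than dusp6, smyhc1, cebpb and cdh2 were chosen after their values were seen. Among those with counts in both groups, the ERK phosphatase gene dusp4 was lower at 121 ± 20.2 against 465 ± 27.3 CPM (DESeq2 adjusted p = 3.91e-07) and so was the Fgf antagonist gene spry4 at 159 ± 45.5 against 505 ± 3.65 CPM (7.46e-05). The leucine zipper transcription factor gene cebpb was lower (6.97 ± 2.1 against 53.8 ± 0.758 CPM, DESeq2 adjusted p = 1.21e-05), as was smyhc1 (0.475 ± 0.672 against 53.05 ± 8.38 CPM, 9.86e-09). The single genes higher included the cadherin gene cdh2 at 221 ± 8.81 against 74.99 ± 15.17 CPM (DESeq2 adjusted p = 0.000242) and the fibronectin gene fn1b at 235 ± 111 against 44.5 ± 4.96 CPM (0.000246). So were col4a1 at 23.8 ± 0.809 against 4.57 ± 1.32 CPM (DESeq2 adjusted p = 1.53e-06) and the follistatin-like gene fstl1a at 45.0 ± 1.61 against 6.52 ± 0.0998 CPM (1.07e-14). The growth factor receptor gene pdgfra stood at 178 ± 20 against 77.8 ± 0.564 CPM (DESeq2 adjusted p = 0.00715). In edgeR none of the genes of this paragraph passed, with adjusted p from 0.45 (fstl1a) to 0.835 (pdgfra). The untreated levels of fstl1a and col4a1 lay near or below the 6.17 and 7.42 CPM estimated for 3 molecules in those libraries. The cyclopamine levels of cebpb and smyhc1 were similarly low (5.58 and 16.3 CPM for 3 molecules in replicates 3 and 4), so these levels are poorly determined. No gene group was tested among these 273 genes.

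As sets, the 51 migration and guidance genes (camera adjusted p = 8.49e-07, and adjusted p = 0.247 with an estimated correlation) and the 47 matrix and receptor genes (8.49e-07, and adjusted p = 0.416 with an estimated correlation) were higher with cyclopamine. None was called over all genes, and over the list alone 0 guidance genes and 2 matrix genes, col4a1 and fn1b, were higher. Both sets were called with each library left out. The summed level of the matrix list was 7714 and 7816 CPM in the untreated libraries, 8020 CPM in cyclopamine replicate 3 and 18978 CPM in replicate 4, so nearly all of its rise in level lay in replicate 4. That library also held 4364 CPM of notochord and floor plate genes, against 92.5 to 123.3 CPM in the other neural crest libraries, and col2a1a, on both lists, stood at 3584 CPM there. The guidance list summed to 2394 and 2480 CPM untreated and to 3418 and 4764 CPM with cyclopamine. The 11 Fgf targets were lower, with dusp6 and spry4 past adjustment over the list alone (camera adjusted p = 0.0471, and adjusted p = 0.637 with an estimated correlation). That list was not called without untreated replicate 1 (0.253), cyclopamine replicate 4 (0.346), slow muscle replicate 1 (0.08) or slow muscle replicate 2 (0.0842), nor with RLE scaling (0.0553). The 20 pigment lineage genes were lower with 0 called over all genes or over the list alone (camera adjusted p = 0.00638, and adjusted p = 0.637 with an estimated correlation). By contrast ednrab, an endothelin receptor gene, stood at 1941 ± 475 against 1138 ± 47.7 CPM. The 17 neural crest genes were not called (camera adjusted p = 0.47). The 13 anterior Hox genes all had a positive fitted change, with 0 called and 0 over the list alone (camera adjusted p = 0.00134, and adjusted p = 0.433 with an estimated correlation; 0.183 without cyclopamine replicate 4). hoxc3a, the most abundant, was at 245 ± 26.4 against 228 ± 6.78 CPM. The 12 trunk Hox genes were higher as a set with 0 called and 0 over the list alone (camera adjusted p = 0.0179, and adjusted p = 0.445 with an estimated correlation). They were not called without untreated replicate 1 (0.0517), untreated replicate 2 (0.0541) or cyclopamine replicate 3 (0.498).

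Markers of other cell types differed between the groups and between the cyclopamine libraries. The 9 myeloid genes all had a negative fitted change (0 called; 1, cebpb, lower over the list alone; camera adjusted p = 1.98e-06, and adjusted p = 0.416 with an estimated correlation). Their summed level was 98.2 and 287 CPM in the untreated libraries against 30.5 and 8.6 CPM with cyclopamine. The 14 erythroid genes were lower as a set (0 called, 0 over the list alone; camera adjusted p = 0.0179, and adjusted p = 0.736 with an estimated correlation), but not without untreated replicate 2 (0.307) or cyclopamine replicate 4 (0.245). Of 8 slow muscle genes 1, smyhc1, was lower over the list alone (0 over all genes; camera adjusted p = 0.0754, and 0.0365 without cyclopamine replicate 4). Of 3 muscle pioneer genes 1, en1b, was lower in the same way (camera adjusted p = 0.0665; 0.0132 without untreated replicate 1), with en1a at 0 counts in all 4 neural crest libraries. The muscle pioneer list summed to only 1.7 and 6.2 CPM in the untreated libraries, below the 6.17 and 7.42 CPM estimated for 3 molecules there. The 18 fast muscle genes (camera adjusted p = 0.0471, and adjusted p = 0.734 with an estimated correlation) and the 48 sarcomere genes (0.0315, and adjusted p = 0.827 with an estimated correlation) were higher as sets. Of their genes 0 were called, and over the list alone 1 each was higher, ryr1b and cav3. Their summed levels in cyclopamine replicate 3 were 1116 and 2651 CPM against 396 and 459.5 CPM in replicate 4. Without replicate 3 neither was called and both turned lower (0.868 and 0.399). Without untreated replicate 1 (0.0524 and 0.104), untreated replicate 2 (0.276 and 0.139), slow muscle replicate 1 (0.115 and 0.0638) or slow muscle replicate 2 (0.112 and 0.0718) neither was called either, and with RLE scaling the fast muscle list was not (0.0527).

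The 8 notochord and floor plate genes were higher as a set with 0 called and 0 over the list alone (camera adjusted p = 0.0471, and adjusted p = 0.637 with an estimated correlation). The notochord sheath collagen gene col2a1a stood at 91.7 CPM in cyclopamine replicate 3 and 3584 CPM in replicate 4, against 77.6 and 59.3 CPM in the untreated libraries. The notochord transcription factor gene tbxta stood at 6.02 and 173 CPM against 6.91 and 6.98 CPM. The list was not called without cyclopamine replicate 4 (0.804), untreated replicate 1 (0.711), slow muscle replicate 1 (0.151) or slow muscle replicate 2 (0.156), nor with RLE scaling (0.0553). The 15 presomitic mesoderm and somite genes, which include tbxta, were higher as a set with 0 called and 1, fgf8a, over the list alone (camera adjusted p = 0.0371, and adjusted p = 0.637 with an estimated correlation). That call was lost without untreated replicate 2 (0.292) or cyclopamine replicate 3 (0.525). The level of fgf8a was 11.3 and 4.56 CPM in cyclopamine replicates 3 and 4 against 0 counts untreated, in replicate 4 below the 16.3 CPM estimated for 3 molecules. All 13 mitochondrially encoded genes had a negative fitted change with 0 called and 0 over the list alone (camera adjusted p = 0.000173, and adjusted p = 0.637 with an estimated correlation). They took 2.19% and 1.2% of counts in cyclopamine replicates 3 and 4. Cytosolic ribosomal protein genes were lower as a set of 89 with 0 called and 0 over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.827 with an estimated correlation). They made up 11.4% of counts in replicate 3 and 5.84% in replicate 4 against 10.1% and 10.6% in untreated neural crest. Without cyclopamine replicate 4 the mitochondrial set was not called (0.0556) and the ribosomal protein set was higher (0.0111).

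The remaining lists were not called as sets, and 0 of their genes were called by edgeR over all genes. Camera adjusted p values were 0.0665 for unfolded protein and amino acid stress, 0.0868 for immediate early and heat shock, 0.153 for endothelium and for pronephros, 0.155 for retinoic acid targets and for posterior Hox genes, 0.201 for neural progenitors and 0.213 for Bmp targets and for Notch targets. They were 0.47 for sclerotome, 0.587 for Wnt targets, 0.629 for myogenic factors and for xenobiotic response, 0.638 for sensory neurons and 0.718 for glia. The largest were 0.738 for the cell cycle, 0.775 for epidermis, for the p53 response and for ventral neural tube and motor neurons, 0.812 for cholesterol synthesis and uptake, and 0.838 for neurons. Several of these depended on a single library. Without cyclopamine replicate 4 endothelial genes (3.61e-10), immediate early genes (0.000805) and posterior Hox genes (0.00468) were lower, and retinoic acid targets (0.00173), epidermal genes (0.0019) and myogenic factors (0.0277) higher. Without cyclopamine replicate 3 the unfolded protein list was higher (0.000134) and epidermis lower (0.0038), and Notch targets were lower without untreated replicate 2 (1.04e-05) and higher without untreated replicate 1 (0.0459). Adjusted over the list alone, cdh17 of the pronephros list was higher, hoxd13a of the posterior Hox list was lower, and 0 genes passed on the others. The level of cdh17 was 6.61 and 6.15 CPM in cyclopamine replicates 3 and 4, against 0 counts untreated. That is near or below the 5.58 and 16.3 CPM estimated for 3 molecules there, so it is poorly determined. Median, mean and test differed in sign for glia and epidermis, and the median was 0.00 for sclerotome and xenobiotic response. The endoplasmic reticulum chaperone gene hspa5 stood at 389.8 and 2853 CPM in cyclopamine replicates 3 and 4, and the keratin gene krt4 at 784 and 52.9 CPM. The Bmp target id1 stood at 270.2 ± 108 against 728 ± 279.6 CPM in untreated neural crest (edgeR adjusted p = 0.835).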

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

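Counts divided by the most common count and DESeq2 without a cyclopamine library were chosen only after the result was seen; all other settings were planned. Where a value moved, the cause was not tested. For slow muscle against untreated neural crest (296 genes higher, 155 lower), counts of genes higher and lower were 981 and 427 without a filter, 1813 and 943 with DESeq2, 1709 and 774 with only the 4 libraries compared, 1264 and 507 with limma, and 1642 and 753 with divided counts (8609 genes tested). Lower genes numbered 249 with robust estimation and 242 with upper quartile scaling. With libraries left out in turn, genes higher ranged from 0 to 1556 and genes lower from 0 to 797. All 451 called genes were called in the same direction without a filter, with the stricter filter, with 4 libraries and with robust estimation, 447 with DESeq2 and 442 with divided counts. For cyclopamine (0 and 0), counts were 8 and 13 without a filter, 153 and 152 with DESeq2, 0 to 145 and 0 to 450 with libraries left out, 1761 and 3288 for DESeq2 without replicate 3, and 647 and 734 for DESeq2 without replicate 4.

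With the replicate block, counts were 161 and 81 in slow muscle, of which 226 genes were shared with the fit without it, and 0 and 0 with cyclopamine. The differences between replicates 1 and 2 in slow muscle and in untreated neural crest correlated across 9854 genes at 0.024 (Pearson) and 0.011 (Spearman). With a single difference per cell type, this cannot decide whether the numbers pair the samples. Lists called by camera numbered 24 in slow muscle and 16 with cyclopamine. Both fell to 0 with an estimated correlation; fry called 17 and 1, RLE scaling 26 and 13, the replicate block left 21 and 10, and libraries left out gave 16 to 26 and 12 to 18. With an estimated correlation camera p rose even where the estimate lay below the preset 0.01. For Hedgehog targets in slow muscle the estimate was -0.329, and unadjusted camera p went from 0.0261 to 0.109. The fall to 0 lists therefore cannot be put down to correlation between genes alone. Lists lost with the replicate block were Hedgehog targets (adjusted p = 0.0766), sclerotome (0.0615) and erythroid genes (0.0604) in slow muscle, and fast muscle (0.202), sarcomere (0.182), presomitic mesoderm (0.108), notochord (0.202), erythroid (0.0751) and Fgf targets (0.0761) with cyclopamine.

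Reversed lists, all in the cyclopamine comparison, were fast muscle (adjusted p = 0.868) and sarcomere genes (0.399), both lower without cyclopamine replicate 3; epidermis (0.0019) and ribosomal proteins (0.0111), higher without cyclopamine replicate 4; and Notch targets (0.0459), higher without untreated replicate 1. With each library left out in turn their adjusted p ranged from 2.23e-05 to 0.868 (fast muscle), 3.61e-10 to 0.399 (sarcomere), 0.0019 to 0.872 (epidermis), 5.61e-15 to 0.0421 (ribosomal proteins) and 1.04e-05 to 0.936 (Notch). Reversed genes in that comparison were actc1b (log2 fold change -4.66 in edgeR and -4.58 in DESeq2 without replicate 3; -4.66 to 2.07 in edgeR over all libraries left out), scube2 (-2.47), eya1 (-2.25), krt4 (-2.25) and col1a1a (-1.62) in DESeq2 without replicate 3, and prdm1a (-0.48) in DESeq2 without replicate 4. No named gene called in slow muscle changed direction in any setting run. The median standard error was 0.54 log2 units over genes with at least 10 CPM in untreated neural crest.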

Other observations

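The tests of the count gap, of notochord cells, of the source of the notochord genes and of muscle transcripts were chosen only after the result was seen; the test of the number of detected genes in cyclopamine replicate 4 was set beforehand. Notch target genes differed between libraries of the same cell type. Their summed level was 2043 and 788 CPM in slow muscle replicates 1 and 2 and 2180 and 313 CPM in untreated neural crest replicates 1 and 2, and 335 and 1063 CPM in cyclopamine replicates 3 and 4. The hairy-related genes her12 (212 and 2.84 CPM in untreated replicates 1 and 2) and her6 (592 and 89.3 CPM) were among them. In slow muscle the keratin gene krt4 stood at 4351 and 6228 CPM and the endothelial cadherin gene cdh5 at 452 and 498 CPM, both outside the muscle lineage that the prdm1a reporter is said to mark.

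All 6 libraries held fewer genes at 11 to 15 counts than at a local peak further up, and many zeros against high counts in the replicate. A filter by the authors that set low counts to 0 was predicted to leave no gene at 0 against at least 100 counts in the replicate. The library with the fewest had 122. Such genes can arise with or without a filter, so that test cannot decide. Each library also held 559 to 618 genes at 1 to 9 counts, which argues against a filter that set all such counts to 0. A candidate explanation is few starting molecules, each amplified into many reads: the variance between replicates divided by the mean should then be near the peak count, and it was 52.2, 42 and 102.3 in slow muscle, untreated and cyclopamine neural crest, against mean peak counts of 41.5, 37 and 70.5. That test was made on data that had been seen, and biological spread adds to the same index. No biological explanation was tested.

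Cyclopamine replicate 4 had the fewest detected genes and high notochord transcripts. 6 of 8 tested notochord and floor plate genes were highest there among the neural crest libraries (col2a1a 3584, col8a1a 415, tbxta 173, ntd5 98.3, shha 79.0 and foxa2 14.8 CPM), while noto and tbxtb were at 0 counts, so notochord cells in that sort may be a source. The counts of the notochord and floor plate genes there equal 911 peak counts, most of them from col2a1a (76309 counts at a peak count of 102). That argues against sampling of few molecules as the origin of the col2a1a level. The sum does not settle it for the less abundant genes, and foxa2 lay below the 16.3 CPM estimated for 3 molecules in that library. Fewer molecules might account for the few genes detected: 12382 genes were expected and 13249 detected, a difference of -6.5%, outside the 5% set beforehand, but the same calculation missed by -5.9% to -10.9% in the other 3 neural crest libraries, so this cannot be told apart from other causes. Replicate 3, treated alike, stood near the untreated libraries for col2a1a (91.7 against 77.6 and 59.3 CPM) and tbxta (6.02 against 6.91 and 6.98 CPM), which goes against an effect of cyclopamine shared by both treated libraries, while an effect in replicate 4 alone stays open, as untested.

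Slow muscle transcripts were found in untreated but hardly in cyclopamine neural crest libraries. The 5 abundant slow genes summed to 69.8 and 68.4 CPM in the untreated libraries and to 4.75 and 0 CPM with cyclopamine. A sort of replicate 3 cleaner of all muscle was predicted to lower 27 fast muscle and sarcomere genes. Instead 25 of the 27 lay at or above their untreated mean and their sum was 430% of it, which argues against that. In replicate 4, 10 of the 27 did and 7 lay under 20% of it, at a sum of 67%, so such a sort cannot be told apart there. These genes were picked partly for low untreated levels, and the eGFP reporter is said to mark slow fibres, not fast ones. The test therefore cannot decide whether slow muscle alone was kept out more cleanly in either library. Slow muscle cells or their RNA in the untreated sorts may be the source, since the ratio of untreated neural crest to slow muscle spanned 3.66-fold over those 5 genes. Most of them rest on very few molecules, and prdm1a (139 against 1058 CPM) was left out of that test. The 27 fast muscle and sarcomere genes ranged from 0.216% to 2.76% of their slow muscle level. Their sum was 0.891% of it, against 0.141% for the 5 slow genes, so muscle transcripts were not present in a fixed proportion. A loss of slow muscle from the treated embryos would leave less of it to carry over and stays open, as untested.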
